A study of Mus musculus with 6 samples.

How the data were processed

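Total RNA of splenic γδ T cells was extracted with TRIzol, and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. The titles put 3 libraries under WT and 3 under KO. The sort, the age of 6 weeks and the genotypes are from the series' design text, and WT was taken as Usf3 f/f and KO as Usf3 f/f with CD2-cre. The submitters' processing notes name fastp, HISAT2 and HTSeq and the genome build GRCm39. Their versions, roles and settings, the annotation and the use of strand are not given in the sources used here. Without a strand setting, reads of overlapping antisense genes cannot be told from those of the gene itself.

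The deposited gene counts are whole numbers for 19390 gene symbols in 6 columns, 1 per library, with no further normalization. The deposited FPKM values equal these counts divided by the column total and by 1 fixed length per gene in all 19390 genes, with a tolerance of 0.01 bp, so they hold no further information and served only as an alternative scale. Every column matched a library by its title, and no row lacked a gene name. Totals ran from 34644862 to 35806402 counts, and genes with at least 1 count from 16331 to 16454. The most abundant gene, Eef1a1, took 1.05% to 1.10% of a library and mitochondrially encoded genes 1.38% to 1.61%. The γδ TCR genes on the list fixed for them had no row and were not analysed here.

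Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors 0.994 to 1.01), filterByExpr by group, and glmQLFit with glmQLFTest on the label alone. The filter kept 12810 genes and left out 0.0366% of the counts. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The biological coefficient of variation, edgeR's term for the spread between libraries of a label beyond counting error, was 4.16%. The labels do not say whether this spread is between animals. Standard errors are the absolute log2 fold change over the square root of the F statistic, and CPM are deposited counts over the TMM-scaled library size, on the usual CPM scale. Intervals are 95% intervals of the quasi-likelihood fit and cover the spread between libraries. Usf3 was also compared by a two-sided exact permutation test of log2 CPM. With a mean of 2540 Usf3 counts per WT library, counting error alone gives a coefficient of variation of 1.98%, beside 2.51% measured in WT and 4.64% in KO.

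For gene lists, camera from limma 3.58.1 was run with a preset correlation of 0.01 on the 28 of 36 lists that had at least 5 tested genes, with Benjamini-Hochberg adjustment over these lists. It was repeated with an estimated correlation, a setting in which camera also uses far fewer degrees of freedom, those left between libraries. Fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, was an alternative. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

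The rule named Usf3, then the 10 highest and 10 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between labels. From each list it took up to 4 members past the threshold by smallest p, or the 2 with the smallest p where fewer than 2 passed, and for other cell types also the 2 most abundant members. The text leaves out some members of lists that it gives by count, and some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen.

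Pairs of libraries with the same label differed by more than sampling noise (chi-square over its degrees of freedom 3.29 to 7.29, and 15.3 to 17.6 between labels), so none was taken as a repeat deposit of another. This does not show that they came from separate animals. Alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom with and without quality weights, limma-trend on log2 FPKM with pseudocounts of 0.1 and 1 for genes with a mean FPKM of at least 1, no filter, a filter of at least 1 CPM in at least 3 libraries, a robust fit, other thresholds, the replicate number as a block, removal of genes over 1% of a library, removal of other-cell markers, and each library left out. A test against a fold of 1.2 and removal of trends with GC content and gene length were added after the data were seen. GC content came from GENCODE transcripts for the build GRCm38, matched by symbol for 12041 of 12810 tested genes (94.0%).

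No annotation of GRCm39 was used here, so no coordinates are given; GRCm38 served only for names, gene order, GC content and exon lengths. The scripts were tested on simulated counts for KO against WT with 200 of 12810 genes changed. They recovered 44.8% of the genes changed 1.2-fold, 74.6% of those changed 1.5-fold and 86.4% of those changed 2-fold, with no wrong sign, and 3.52% of calls were false. Of 28 simulated lists, 1 was called, the changed one. Each gene was drawn independently there, so this does not test the preset correlation of camera. In the real data the estimated correlation was 0.65 for cytosolic ribosomal protein genes. A simulated GC trend over 12689 genes gave 2889 calls before and 0 after the correction by the same edgeR test.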

Results

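Messenger RNA levels were measured by RNA sequencing in γδ T cells, the T lymphocytes whose antigen receptor is built from γ and δ chains, sorted by flow cytometry from the spleens of 6-week-old mice. Whether the cells were cultured or stimulated between the sort and lysis is not given in the sources used here. The 3 WT-labelled libraries came from mice with floxed Usf3 alleles (f/f), and the 3 KO-labelled libraries from floxed mice that also carried CD2-cre, a transgene that expresses Cre recombinase in lymphoid cells. The deposited counts summed to between 34644862 and 35806402 per library over 19390 gene symbols, and 12810 genes had enough counts to be tested. The design implies 1 comparison, KO against WT, and the series title names the role of Usf3 in these cells as its subject. Only the KO-labelled mice carried CD2-cre, so the comparison holds the transgene and the floxed deletion together.

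Usf3, the targeted gene, encodes a basic helix-loop-helix leucine zipper protein related to the upstream stimulatory factors. Its counts were 2499, 2527 and 2593 in WT replicates 1, 2 and 3 and 2532, 2360 and 2348 in KO replicates 1, 2 and 3. As CPM, the deposited counts scaled to a common library size, this was 72.2 ± 1.81 in WT and 68.5 ± 3.18 in KO (SD, n = 3 each), and KO replicate 1 lay within the WT range. The log2 fold change was -0.076 ± 0.043 (SE), a fall of 5.16% with a 95% interval from -0.936% to 10.9%, and did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.261). A two-sided exact permutation test of log2 CPM gave p = 0.2, where 3 libraries against 3 allow no p below 0.1. In the GRCm38 annotation the Usf3 transcript has 7 exons and 12708 bp, of which the last exon holds 12051 bp (94.8%). The labels do not say which exons were floxed, so a count over the whole gene cannot check the labels, and the libraries are called WT-labelled and KO-labelled for that reason.

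**Figure D1:**
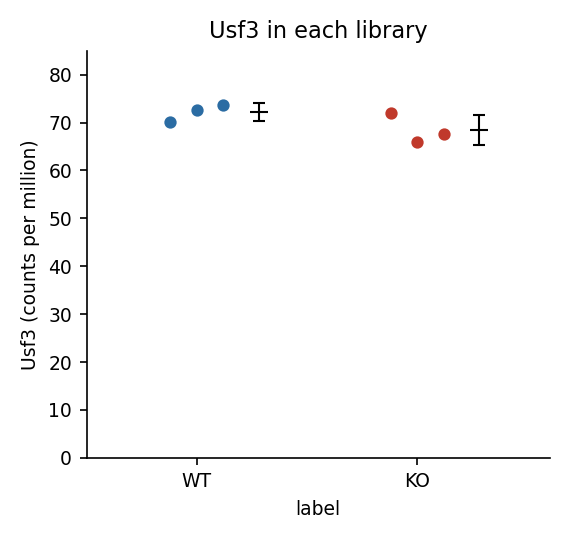
Usf3 level in each library in CPM (vertical axis, starting at 0) by label (horizontal axis); points are libraries and bars are the mean ± SD of 3. The WT mean of 72.2 and the KO mean of 68.5 lie close together and the libraries of the 2 labels overlap.

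Interferon-stimulated genes were lower in KO-labelled cells, and early genes of T cell receptor (TCR) signalling were lower on balance. The largest rise among genes of at least 2 CPM was in the co-repressor gene Tle1. Gbp2, an interferon-induced GTPase, went from 425 ± 3.11 CPM in WT to 229 ± 3.04 in KO, and Egr1, a transcription factor induced within minutes of TCR engagement, from 711 ± 14.8 to 358 ± 3.86 (SD, n = 3 each). Tle1, a Groucho-family co-repressor, went from 5.01 ± 0.795 to 26.5 ± 1.66 CPM, a 5.29-fold rise. Genes of naive T cells and tissue homing, of type 1 and type 17 effector programmes, and of cholesterol and fatty acid synthesis were also lower on balance. Altogether 2219 of 12810 genes (17.3%) changed at an adjusted p under 0.05 by edgeR, 926 higher and 1293 lower in KO-labelled libraries. The excess of lower genes depended on scaling, with 1091 higher and 1214 lower by upper-quartile scaling.

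Most of these changes were small. Only 382 genes changed by at least 1.5-fold, 159 higher and 223 lower, and 158 by at least 2-fold, 78 higher and 80 lower. The median absolute log2 fold change of the 2219 genes was 0.24. The 3 KO-labelled libraries lay wholly above or wholly below the 3 WT-labelled ones in 4117 tested genes, 32.1% where chance gives 10%, and 2174 of these were among the changed genes. The first principal component, with 37.8% of the variance of log2 CPM, separated the labels. The second, with 21.1%, spread the KO-labelled libraries, with scores from -24.9 for KO replicate 2 to 16.8 for KO replicate 3, while the WT-labelled ones lay between -4.74 and 2.74. The chi-square of counts over genes, divided by its degrees of freedom, was 3.62 to 7.29 between KO-labelled libraries, highest for replicates 2 and 3, and 3.29 to 3.33 between WT-labelled ones.

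**Figure D2:**
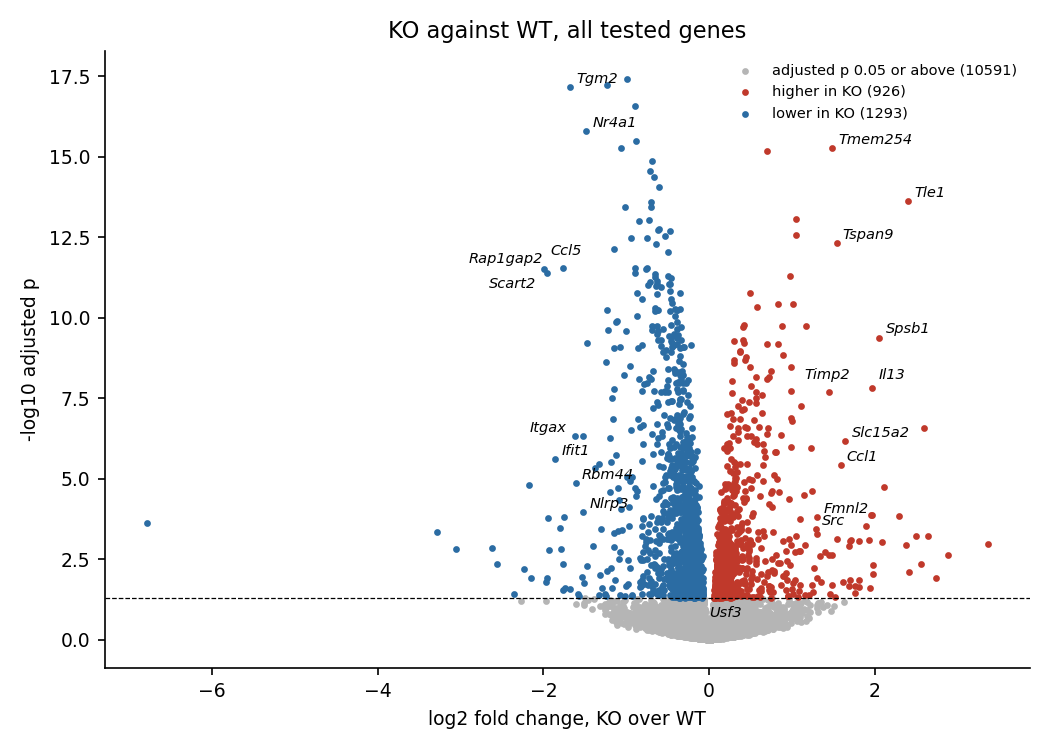
Log2 fold change of KO over WT (horizontal axis) against -log10 of the adjusted p (vertical axis) for 12810 tested genes; red points are the 926 genes higher and blue points the 1293 genes lower in KO, grey points did not pass, and the dashed line marks an adjusted p of 0.05. Usf3 lies below the line, and the point far to the left is Syce1, a gene with 41 counts over the WT libraries and 0 over the KO libraries.

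Among the 10 genes with the largest rise at a mean of at least 2 CPM, Tle1 (log2 fold change 2.40 ± 0.098, SE) was followed by Spsb1 (2.06 ± 0.149), which encodes a SOCS-box adaptor of ubiquitin ligases, and by the type 2 cytokine gene Il13 (1.97 ± 0.177). Il13 stood at 1.86 ± 0.460 CPM in WT and 7.29 ± 0.697 in KO (SD, n = 3 each). Ccl1, the gene of a chemokine that acts on CCR8, rose by 1.59 ± 0.205, and Slc15a2, a peptide transporter gene, by 1.64 ± 0.188. Tmem254, at 35.1 CPM in WT, and Tspan9, a tetraspanin gene, rose by 1.48 and 1.54. Timp2, a metalloproteinase inhibitor gene, the formin gene Fmnl2 and the kinase gene Src completed the set with rises of 1.45, 1.30 and 1.29. Their adjusted p ranged from 5.47e-16 for Tmem254 to 0.000373 for Src (edgeR).

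Among the genes with the largest fall at the same level, Rap1gap2, whose product switches off the GTPase Rap1, fell by 1.99 on the log2 scale, and the scavenger receptor gene Scart2, a marker of interleukin-17-producing γδ T cells, fell by 1.96. Ifit1, an interferon-induced gene, fell by 1.86, the chemokine gene Ccl5 by 1.77 and the transglutaminase gene Tgm2 by 1.67. Tgm2 went from 106 ± 1.97 to 33.4 ± 1.21 CPM, and Ccl5 from 20.1 ± 0.939 to 5.92 ± 0.631 (SD, n = 3 each). The integrin gene Itgax (CD11c), the RNA-binding protein gene Rbm44 and the inflammasome sensor gene Nlrp3 fell by 1.62, 1.61 and 1.52, each from under 8 CPM in WT. Nr4a1, a nuclear receptor gene used as a reporter of TCR signalling, fell by 1.49, from 106 ± 2.24 to 37.9 ± 2.29 CPM. The adjusted p of these genes ran from 6.80e-18 for Tgm2 to 0.000109 for Nlrp3 (edgeR).

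**Figure D3:**
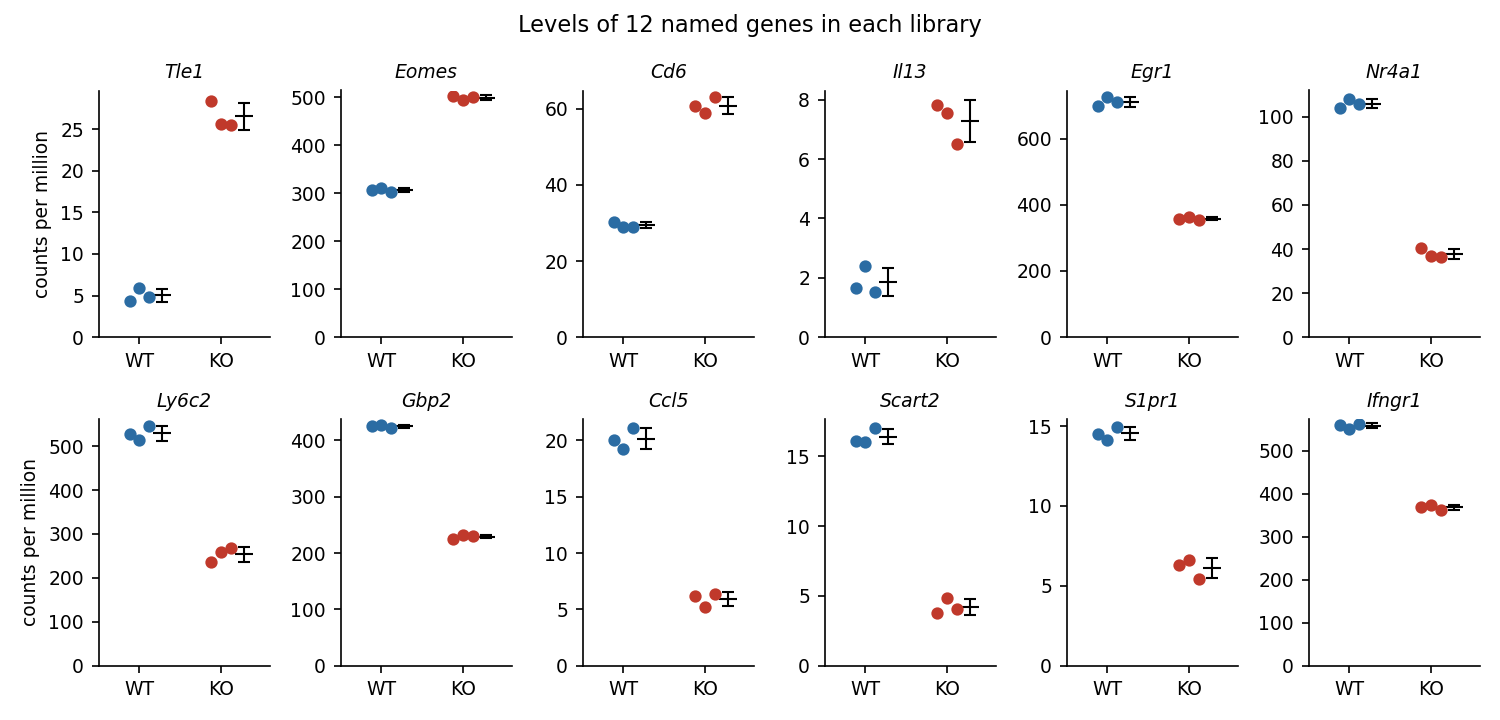
Level of 12 named genes in each library in CPM (vertical axes, all starting at 0) by label; points are libraries and bars are the mean ± SD of 3 libraries. The WT and KO points of each of the 12 genes are apart, for example Egr1 at means of 711 and 358.

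Interferon-stimulated genes fell in nearly all tested members. Of 40 tested members, 37 were lower and 0 higher in KO-labelled libraries over all genes tested, and 40 were lower when adjusted over the list alone, with a median log2 fold change of -0.53. The guanylate-binding protein genes Gbp2 and Gbp6 changed by -0.89 ± 0.025 and -0.70 ± 0.029 (SE), and the immunity-related GTPase genes Iigp1 and Igtp by -0.84 ± 0.037 and -0.54 ± 0.025. Of 2 members chosen after their values were seen, Irf7, a transcription factor gene of the interferon response, changed by -0.53 and Isg15 by -1.19. The list was lower by camera (adjusted p = 7.72e-69), and the call held with an estimated correlation (adjusted p = 0.00135). Summed over the 40 genes, the level was 5808 ± 15.6 CPM in WT and 4189 ± 34.0 in KO (SD, n = 3 each). Markers of B cells, monocytes, dendritic cells and neutrophils were also lower in sum, which was not tested, from 145 ± 4.92 to 125 ± 4.19 CPM over 63 genes, with all 3 tested monocyte markers lower.

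Early genes induced by TCR signalling were lower in 9 of 18 tested members and higher in 1, or lower in 9 and higher in 3 adjusted over the list alone. Egr1 changed by -0.99 ± 0.024 (SE), Nr4a1 by -1.49 ± 0.046, Myc, a growth-promoting transcription factor gene, by -0.62 ± 0.028, and Spry2, a feedback inhibitor gene of the Ras pathway, by -0.72 ± 0.041. Of members chosen after their values were seen, Nr4a2, Nr4a3 and Egr3 did not pass, at 0.019, -0.097 and -0.091, and Tnfaip3 rose by 0.43. The camera adjusted p was 2.67e-22, and 0.0231 with an estimated correlation. The list of immediate early and dissociation stress genes, which shares 0 members with this list and serves as a sign of handling, moved with it, with 11 of 23 lower and 4 higher (12 and 6 adjusted over the list alone). Ier2, Zfp36, Btg2 and Fos fell there by 0.64, 0.47, 0.69 and 1.00, while Dusp1 and Nfkbia, chosen after their values were seen, were higher by 0.51 and 0.35. Its camera adjusted p was 2.11e-06, and 0.0231 with an estimated correlation. Genes of TCR signalling itself, 6 higher and 11 lower of 32 (7 and 14 adjusted over the list alone), were not called as a list (adjusted p = 0.856). Within it Cd6, the gene of a co-receptor that tunes TCR signals, rose by 1.05 ± 0.049 and Ptpn6, the phosphatase SHP-1, by 0.22, and the adaptor gene Sla fell by 0.34.

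**Figure D4:**
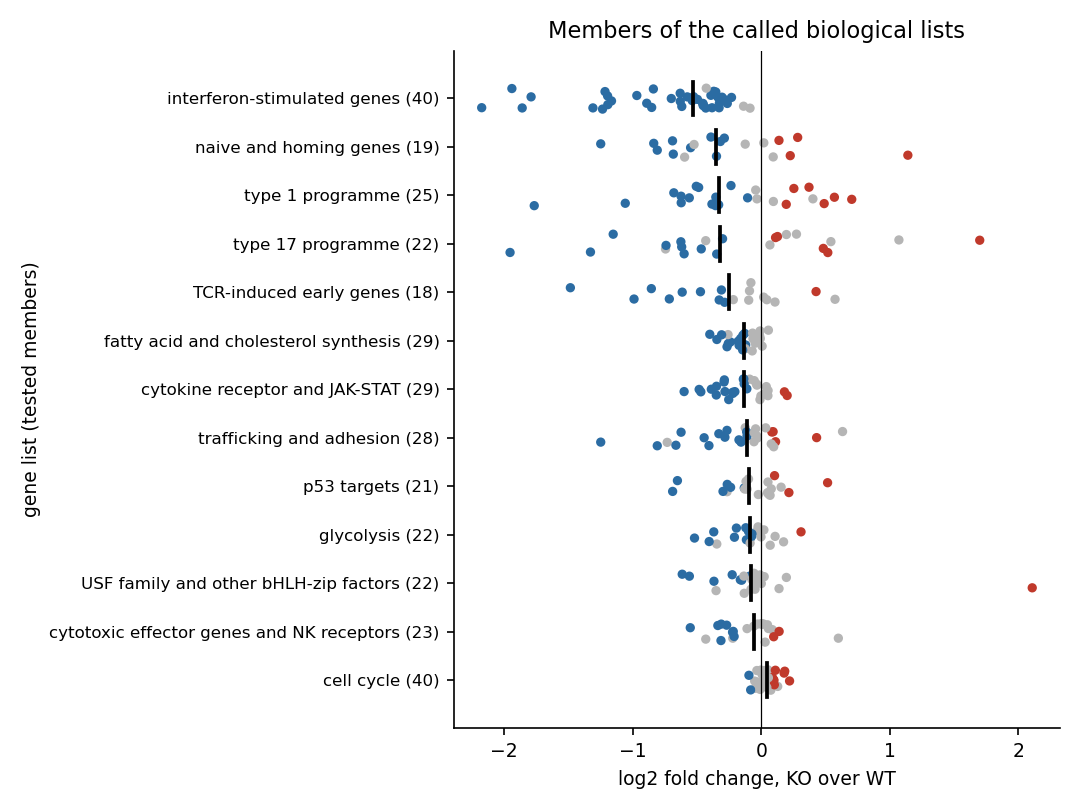
Log2 fold change of KO over WT (horizontal axis) of the tested members of 13 biological gene lists called by camera (vertical axis, number tested in brackets); red and blue points are members higher and lower at an adjusted p under 0.05, grey points did not pass, and black bars are medians. The interferon-stimulated list has the lowest median, -0.53, and the cell cycle list the highest, 0.042.

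The type 1 programme, the genes of interferon-γ-producing lymphocytes, held members that moved in opposite directions, with 15 of 25 lower and 6 higher (15 and 8 adjusted over the list alone). Ly6c2, a surface antigen gene of memory-like T cells, fell by 1.06 ± 0.035 (SE) and Ccl5 by 1.77, while the T-box factor gene Eomes rose by 0.70 ± 0.024 and the chemokine gene Xcl1 by 0.49 ± 0.029. Tbx21, the T-box factor T-bet, and Ifng, both chosen after their values were seen, changed by -0.51 and 0.25. The list was lower by camera (adjusted p = 3.29e-09; adjusted p = 0.0231 with an estimated correlation). Cytotoxic effector genes and NK receptors had 8 of 23 lower and 2 higher (9 and 3 adjusted over the list alone). Gzmb, which encodes granzyme B, fell by 0.22 from 7044 ± 107 CPM, the activating receptor gene Klrk1 (NKG2D) by 0.31 and Cd244a by 0.31, and Gzma, chosen after its value was seen, rose by 0.14. Their camera call (adjusted p = 0.0148) was lost with an estimated correlation (adjusted p = 0.289) and without WT replicate 3 (adjusted p = 0.0652).

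The type 17 programme, the genes of interleukin-17-producing cells, had 10 of 22 tested members lower and 5 higher (12 and 7 adjusted over the list alone). Besides Scart2, the nuclear receptor gene Rora fell by 0.63 ± 0.060 (SE), the calcium-binding protein gene S100a4 by 0.47 ± 0.030 and the interleukin-18 receptor gene Il18r1 by 0.35 ± 0.026. The camera adjusted p was 0.000532, and 0.0460 with an estimated correlation. Il17a itself was under the count filter, with 9, 14 and 26 counts in WT and 2, 5 and 4 in KO replicates 1, 2 and 3.

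Naive and homing genes were lower in 10 of 19 members and higher in 4 (11 and 5 adjusted over the list alone). The 4 higher members were Als2cl, Satb1, Bach2 and Foxp1, at 1.14, 0.28, 0.23 and 0.14. S1pr1, the receptor gene for exit from lymphoid organs, changed by -1.25 ± 0.101 (SE), Igfbp4 by -0.69 ± 0.047, and the membrane protein genes Ms4a6b and Ms4a4b by -0.39 and -0.35. Klf2, a transcription factor gene that drives S1pr1, was chosen after its value was seen and changed by -0.84. Trafficking and adhesion genes, 3 of which the naive list also holds, were lower in 13 of 28 and higher in 4 (13 and 4 adjusted over the list alone). The integrin gene Itgb7 changed by -0.66 ± 0.025 and the chemokine receptor gene Cxcr3 by -0.62 ± 0.044, while Itgae (CD103) rose by 0.43 ± 0.034. The camera adjusted p was 9.49e-07 for the naive and 4.91e-06 for the trafficking list, and 0.0231 for each with an estimated correlation.

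Cytokine receptor and JAK-STAT genes were lower in 17 of 29 members and higher in 2 (17 and 3 adjusted over the list alone). Ifngr1, a chain of the interferon-γ receptor, went from 559 ± 5.78 to 369 ± 5.11 CPM (SD, n = 3 each; log2 fold change -0.60), and the kinase gene Pim2, Smad3, which carries TGF-β signals, and Il10ra changed by -0.35, -0.47 and -0.29. The camera adjusted p was 1.23e-07, and 0.0231 with an estimated correlation. Activation and checkpoint genes were mixed, with 8 of 25 lower and 7 higher (9 and 8 adjusted over the list alone) and no list call (adjusted p = 0.150). Their members Cd69, Ctla4, Il2ra and Pdcd1 were all lower, with log2 fold changes of -0.47, -0.61, -0.32 and -0.38. Among the 7 higher members, Izumo1r, Cd200, Tox and Tigit, chosen after their values were seen, changed by 1.27, 0.94, 0.65 and 0.43; the Cd200 call was lost without WT replicate 1 or KO replicate 2 (edgeR adjusted p = 0.0633 and 0.0547).

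Fatty acid and cholesterol synthesis genes were lower in 16 of 29 members and higher in 0 (17 and 1 adjusted over the list alone), with small changes around a median of -0.14. The fatty acid elongase gene Elovl6 changed by -0.40 ± 0.035 (SE), and Insig1, a feedback regulator gene of cholesterol synthesis, by -0.27 ± 0.031. The camera adjusted p was 5.87e-08, and 0.0263 with an estimated correlation. Glycolysis genes were lower in 11 of 22 and higher in 1 (13 and 2 adjusted over the list alone), among them the glucose transporter gene Slc2a3 at -0.52, Hk2 at -0.41, Slc16a3 at -0.37 and Pfkp at -0.21. The glycolysis call (camera adjusted p = 0.000213) was lost with an estimated correlation (adjusted p = 0.252). In the list fixed for the USF family and other bHLH-zip factors, 7 of 22 were lower and 1 was higher. Adjusted over the list alone, these counts were 8 and 3. The list also holds bHLH genes without a leucine zipper: Clock, Ahr, the lower Bhlhe40 and Hif1a, and the higher Bhlhe41. Usf1 and Usf2 themselves did not pass (edgeR adjusted p = 0.355 and 0.0775). The list's camera call (adjusted p = 0.00483) was lost with an estimated correlation (adjusted p = 0.0984). Myc, Mxd1 and Srebf2, the cholesterol regulator, changed by -0.62, -0.37 and -0.16 there, and Bhlhe41 rose by 2.11 ± 0.304 from 0.558 ± 0.165 CPM.

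Of p53 targets, 6 of 21 were lower and 3 higher (7 and 3 adjusted over the list alone), with Ddit4, Btg2 and Cdkn1a at -0.65, -0.69 and -0.30 and Zmat3 at 0.22. Their call (camera adjusted p = 0.0377) was lost with an estimated correlation (adjusted p = 0.162), under the stricter low-count filter (adjusted p = 0.0556) and without KO replicate 3 (adjusted p = 0.0954). Cell cycle genes were higher in 9 of 40 and lower in 2, counts that were equal adjusted over the list alone, with Tyms, Ccnb1, Tk1 and Mcm5 at 0.22, 0.18, 0.18 and 0.11. Their camera call (adjusted p = 0.0215) was lost with an estimated correlation (adjusted p = 0.214). Cytosolic ribosomal protein genes were higher in 12 of 51 and lower in 0, also when adjusted over the list alone, with Rps2 and Rpl15 at 0.098 and 0.12. That call (camera adjusted p = 0.00333) was lost with an estimated correlation (adjusted p = 0.775), by fry (adjusted p = 0.172) and without KO replicate 3 (adjusted p = 0.0598).

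The remaining lists were not called. Oxidative phosphorylation genes were higher in 7 of 45 and lower in 0 (adjusted p = 0.105), mitochondrially encoded genes higher in 1 of 13 (adjusted p = 0.137), and fatty acid oxidation genes higher in 3 and lower in 2 of 23 (adjusted p = 0.548). NRF2, glutathione and glutamine genes were higher in 3 and lower in 2 of 28 (adjusted p = 0.252), with Gclc, the rate-limiting enzyme of glutathione synthesis, at 0.31 and Prdx6 at 0.22. Lysosome and autophagy genes were lower in 2 of 26 (adjusted p = 0.795), and unfolded protein and integrated stress response genes higher in 4 and lower in 5 of 25 (adjusted p = 0.695). Apoptosis and survival genes were higher in 5 and lower in 6 of 30 (adjusted p = 0.989), with the opposed genes Bcl2l11 (BIM) and Bcl2l1 (BCL-XL) both higher, by 0.22 and 0.28. Regulators of the γδ lineage were higher in 4 and lower in 5 of 23 (adjusted p = 0.989), with Ets1 at 0.30 and Tcf7 and Lef1 at -0.32 and -0.68. Adjusted over the list alone, the higher and lower counts were 7 and 0, 1 and 0, 3 and 2, 6 and 2, 0 and 2, 5 and 6, 5 and 8, and 6 and 6 in the same order of these 8 lists. Median, mean and test differed in sign for the activation, TCR signalling, γδ lineage and apoptosis lists.

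Markers of other cell types moved in both directions and differed in level. B cell markers were changed in 0 of 4 tested members by edgeR, with Cd74 at 12.5 ± 1.17 CPM in WT and 14.3 ± 1.48 in KO (SD, n = 3 each; adjusted p = 0.186, and 0.0469 without KO replicate 2) and Cd79b at 5.65 ± 0.194 and 5.24 ± 1.10. The 3 tested monocyte and macrophage markers were lower in KO, Axl from 22.8 ± 1.22 to 18.4 ± 0.553 CPM, Cd68 from 8.36 ± 1.15 to 6.20 ± 0.400 and Itgam from 1.55 ± 0.345 to 0.630 ± 0.413. The Cd68 call was lost without WT replicate 2 or 3 (adjusted p = 0.130 and 0.0734), and the Itgam call in 4 of the 6 fits that left out a library. Dendritic cell markers were lower in 2 of 9 (camera adjusted p = 0.265, and 0.00802 by fry), with Itgax among them and Cst3 at 55.6 ± 0.949 and 49.2 ± 2.08 CPM, whose call was lost without KO replicate 1 (adjusted p = 0.0714). NK cell markers were higher in 2 and lower in 5 of 13 (camera adjusted p = 0.552), with Fcer1g at -0.38 and Klrb1f at 0.70. Of 5 αβ T cell markers, 1 was higher and 2 were lower (camera adjusted p = 0.989, again with a median and a test of opposite sign): Cd8a went from 66.1 ± 0.527 to 86.9 ± 2.41 CPM and Foxp3 from 12.3 ± 1.01 to 8.31 ± 0.388, while Cd8b1 stood at 18.1 ± 0.521 and 17.8 ± 0.496. Only 6 of the 14 αβ T cell symbols on the list had a row, so the content of αβ T cells cannot be judged from it. Erythroid markers were higher in 1 of 3, platelet markers higher in 1 of 2 and stromal markers lower in 1 of 3. The most abundant of the erythroid, platelet and stromal markers were the transferrin receptor gene Tfrc, which dividing cells also express, at 610 ± 15.4 and 587 ± 34.3 CPM in WT and KO, the integrin gene Itgb3 at 124 ± 3.50 and 137 ± 4.32, and Pecam1 at 57.7 ± 5.88 and 44.0 ± 2.00. NK markers summed to 192 CPM in WT and 173 in KO, and no neutrophil marker had enough counts. Adjusted over the list alone, the higher and lower counts were 0 and 0 for B cells, 0 and 3 for monocytes, 0 and 2 for dendritic cells, 3 and 6 for NK cells, 1 and 2 for αβ T cells, 1 and 1 for erythroid, 1 and 0 for platelet and 0 and 1 for stromal markers. Xist, the 1 sex-linked gene tested, was at 1195 ± 39.0 CPM in WT and 1133 ± 71.2 in KO (adjusted p = 0.108, and 0.00107 without KO replicate 2).

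Of 28 lists with at least 5 tested genes, camera called 15, 13 lower and 2 higher, and 9 of the 15 held with an estimated correlation. Splits of the libraries into 3 and 3 that mix the labels also called lists with the preset correlation, from 1 to 7 each. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. Genes with near-identical copies, such as the Gbp, Iigp1 and Igtp, Ms4a, Klr and granzyme families, are uncertain, since it is not stated how reads that match several copies were counted.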

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

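The 1.2-fold test and the GC and length correction were chosen after the data were seen. The count of 2219 changed genes stayed within 1.5 times under every other tool, scaling, filter, weighting and correction run, from 1702 (FPKM with a pseudocount of 1) to 2678 (GC and length trend removed); a threshold of 0.1 gave 2854. The excess of lower genes (926 higher, 1293 lower) shrank with upper-quartile scaling (1091 and 1214), total counts (1093 and 1222) and GC and length trends removed (1290 and 1388). No shared call had the opposite sign in any of these settings. By their own construction stricter criteria gave fewer genes: 158 at 2-fold or more (78 higher, 80 lower), and 447 when tested against a 1.2-fold change (147 higher, 300 lower). Leaving out 1 library gave 1660 to 2256 genes. Usf3 stayed on the same side of the threshold in every setting other than the 1.2-fold test, which was not read for single genes. Its log2 fold changes ran from -0.114 to -0.049 as libraries were left out. Of 15 lists, 9 were called with an estimated correlation, a setting that also lowers the degrees of freedom. These effects were not separated. The interferon list, with an estimate of 0.0068, went from a camera adjusted p of 7.72e-69 to 0.00135. A correlation above the preset 0.01 is not the reason for the p53 and USF family lists. Their estimates were -0.0058 and 0.0081. Fry called 17, and leaving out 1 library gave 14 to 16.

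With the replicate number as a block, 1969 genes and 15 lists were called and Usf3 was at -0.077. Deviations of same-numbered libraries correlated at 0.055, -0.022 and -0.039, and those of differently numbered ones at -0.055 to 0.079. No pairing by number was seen, and not every library correlated best with its own number. With 3 libraries per label and values this small, a shared litter or day cannot be excluded.

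Over all settings other than the 1.2-fold test, named genes kept call and direction in 3456 comparisons. They gained the call in 19 and lost it in 136, mostly at the 2-fold threshold. In 1 comparison the sign changed: Cd8b1, not called, at 0.00077 without KO replicate 3 (-0.042 to 0.00077 as libraries were left out). For 3 lists that were not called, the test turned direction and the cause was not tested. The γδ lineage list did so without WT replicate 2 or KO replicate 3 (medians -0.041 and -0.054, within -0.063 to -0.034 over the libraries left out). The apoptosis list did so by fry (-0.0166), under the block (-0.0165) and without WT replicate 2 or KO replicate 2 (-0.022 and -0.029, within -0.029 to -0.0098). The αβ T cell list did so by fry (-0.17) and without WT replicate 1 (-0.245, within -0.255 to 0.063). Changes near 1.2-fold may be missed in part: 44.8% were recovered in simulated data with 200 of 12810 genes changed. With 2219 genes called in the real data the adjusted threshold is less strict, so that share need not hold here.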

Other observations

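The gene families below, the genes beside them and the tests on Usf3, RNA of other cells, heat shock genes and gene order were chosen only after the results were seen, and the correction for GC content and length was added after the data were seen, with its bounds set before its result. The 5 families looked at were picked with their values in view, so their tests describe and do not check. All 8 tested Gimap genes, GTPases of lymphocyte survival, were lower in KO-labelled libraries (median log2 fold change -0.44; Fisher's exact test of lower genes against all other tested genes, two-sided p = 1.06e-08). Gimap4 went from 765 ± 21.6 to 542 ± 13.6 CPM and Gimap6 from 259 ± 4.31 to 171 ± 0.993 (SD, n = 3 each). Of 10 PYHIN genes, the interferon-induced DNA sensors of the Ifi200 cluster, 8 were lower and 0 higher (median -0.59), with Ifi203 at -0.42. Of 9 granzyme genes, 6 were higher and 1 lower (median 0.26), with Gzmc, Gzmd and Gzmf at 0.26, 0.34 and 1.00 against the fall of Gzmb; the fixed cytotoxic list also holds Gzma, Gzmb, Gzmk and Gzmm. Of 18 Dusp genes, 4 were higher and 3 lower (median -0.048), and of 4 Klra genes 1 was lower. The medians of all 5 kept their sign under RLE, upper-quartile and total-count scaling. The Gimap, PYHIN, granzyme and Klra families hold similar copies whose reads the counting could have split.

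Tle2, a second Groucho co-repressor gene, rose with Tle1, from 0.531 ± 0.075 to 3.23 ± 0.519 CPM (SD, n = 3 each; edgeR adjusted p = 2.70e-07). Trat1, an adaptor gene of the TCR complex, rose by 1.96 ± 0.331 (SE), from 0.455 ± 0.088 CPM. Syce1, a gene of the meiotic synaptonemal complex, had 14, 12 and 15 counts in WT and 0 in every KO library, at least 13.6-fold lower against a floor of 3 counts over the group. Il17a, under the filter, was lower in a fit without a filter (log2 fold change -2.12, edgeR adjusted p = 0.0225), from 49 counts over the WT and 11 over the KO libraries. Il17f, with 19 and 10 counts, did not pass in that fit (-0.91, edgeR adjusted p = 0.632). The Usf3 relatives Usf1 and Usf2 stood at -0.080 and -0.14 and did not pass (edgeR adjusted p = 0.355 and 0.0775), but Usf2 passed without KO replicate 3 (adjusted p = 0.0121), with GC and length trends removed and by limma-voom with quality weights. Mki67, a gene of dividing cells, was at 1603 ± 11.3 CPM in WT and 1567 ± 16.6 in KO, and Gzmb was at 7044 ± 107 CPM in WT and 6057 ± 78.8 in KO. The 40 cell cycle genes summed to 13229 CPM in WT and 13385 in KO. Such levels of genes of dividing cells argue against a mostly resting population under either label. The labels do not say whether the sorted cells were cultured or stimulated before lysis, so whether division began in the spleen is not settled.

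The first pattern is that Usf3 reads were nearly as high in KO-labelled as in WT-labelled libraries. Against 1 wrongly labelled library, 0 of 6 libraries had their nearest neighbour under the other label; distances in log2 CPM ran from 36.0 to 44.0 within and from 45.7 to 49.4 between labels. A deletion of exons before the last exon may remove only 5.17% of the annotated transcript; the interval of the fall in Usf3, -0.936% to 10.9%, holds that share and also 0. A deletion that leaves the last exon and no deletion at all cannot be told apart from gene counts, since the floxed exons are not given.

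The second pattern is the fall of interferon-stimulated genes. After the trends with GC content and gene length were removed, their median log2 fold change was -0.54 against -0.53 before, which argues against these trends. RNA of B cells, monocytes, dendritic cells or neutrophils in WT-labelled libraries is unlikely as the whole source: their 63 markers were also lower in sum, by more than the SD of either label, but by only 19.8 CPM beside an excess of 1618 CPM over the 40 interferon-stimulated genes, so a small contribution stays open. Of the 63 markers, 12 reached 1 CPM, led by Cst3 at 55.6 and 49.2 CPM, and Lyz2 had at most 14 counts in a library, after a γδ T cell sort. Markers of αβ T cells and NK cells were not among the 63, so RNA of those cells was not tested here. Open and untested are the Usf3 deletion, the Cre transgene itself, the mix of γδ subsets, and a processing batch, which the labels do not give and which cannot be told apart from the label.

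The third pattern is the fall, on balance, of TCR-induced early genes together with immediate early genes. Handling stress that raises heat shock and AP-1 genes together predicts a fall of both, but the 7 tested heat shock members had a median log2 fold change of 0.042, within a range of 0.022 to 0.20, and 2 of them, Hsph1 and Dnaja1, were higher. This argues against that kind of handling difference, while one that acts on immediate early genes alone stays open. The Usf3 deletion, the Cre transgene and a batch stay open here too, as untested.

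A local effect around the targeted locus was also tested: of the 40 tested genes nearest to Usf3 in GRCm38 gene order, 22.5% were changed, above the median window of 40 genes (17.5%) at percentile 82.3, but below the 30% that marks the top 5% of windows.

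The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2219 genes, and 1 of the 10 splits, the real one, gave as many. The highest of the others gave 0. Each of the others mixes the labels, so any difference between labels widens the spread within its groups. Few calls are then expected whatever the cause of the difference, and the 0 does not bear on that cause. For gene lists the real split gave 15, and again 1 of the 10 splits gave as many. Each of the others called some lists, from 1 to 7, though it called 0 genes.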
